A study of Mus musculus with 51 samples.

How the data were processed

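Gene expression was measured on 1-colour Affymetrix-type arrays in whole lung of male mice aged 6 to 8 weeks. The mice were BALB/c, C57BL/6, or B-cell deficient mice that lack a functional immunoglobulin heavy chain mu gene on a C57BL/6 background. Per the labels, the skin of every mouse was exposed on 2 occasions to 1% methylene diphenyl diisocyanate (MDI, a monomer of polyurethane production that can sensitize the airways). On days 15, 16, 19 and 20 the mice received either MDI-glutathione reaction products or a control solution through the nose, and perfused, lavaged lungs were taken 48 h after the last exposure. Crofelemer, a chloride channel inhibitor, was given to some mice at 4 mg/kg through the nose 4 h before each exposure. Total RNA was extracted with a Qiagen kit and 250 ng were labelled with biotin.

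The authors deposited log2 signal values for 22206 probe sets on 51 arrays, written with Transcriptome Analysis Console, with 2 decimals. The version of that program and its normalization are not given in the sources used here. The log base is not stated in the labels and was inferred from the range of the values. The largest deposited value was 20.91, above 16, the log2 of the largest 16-bit reading, so fold changes hold for the deposited scale and need not be ratios of raw readings. The means of the arrays fell into 4 levels, one each for BALB/c mice, C57BL/6 mice without crofelemer, C57BL/6 mice with crofelemer, and B-cell deficient mice. The sets thus look separately normalized, though the levels of the C57BL/6 arrays lie close (highest with crofelemer 7.476, lowest without 7.480), and separate processing of these was not shown. A comparison within a set is untouched by this, and a comparison across sets carries any difference in processing. A difference between the effects of MDI in 2 sets cancels a shift that is shared by a whole set, but not a difference in scale or spread between the sets. No deposited value was rescaled.

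Of the 51 arrays, 49 entered the comparisons in 8 groups. The title and the other labels of the remaining 2 arrays contradict each other on the treatment, and these arrays were left out as unassigned. The submissions fell into 3 blocks of consecutive records, called lots here, which may mark batches but are not named as such in the labels. Array number is the limit on precision, since arrays give no counts.

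Gene names came from the annotation of the array. Of the 22206 probe sets, 19572 carried 1 gene symbol and 2634 carried none. Where several probe sets measured a gene, which held for 55 symbols, the one with the highest mean over the 49 arrays stood for it. Comparisons used limma 3.58.1 in R 4.3.3, with 1 model of 8 group means (41 residual degrees of freedom), an intensity trend in the moderated variance, and 2-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all 22206 probe sets, and probe sets with an adjusted p under 0.05 are counted as changed. Values are log2 fold changes ± the moderated SE, or group means ± SD. The 10 comparisons share control groups, so their chance values are shared as well.

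Before the data were examined, 33 gene lists, the comparisons, the processing alternatives and a rule for named genes were fixed. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 33 lists within a comparison, and again with an estimated correlation. Some lists share members, at most 3 for any pair. The rule for named genes took, in each comparison, up to 8 genes with the largest rise and up to 8 with the largest fall among changed genes with a proper name, up to 4 members with the smallest adjusted p of each list described, and 9 genes chosen in advance for the airway response, with the B-cell genes Ms4a1 and Cd79a in the comparisons of B-cell deficient mice. Which lists are described with their members was decided after the list results were seen. Genes outside the rule are marked where they appear. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

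The procedure was tested on simulated data with 200 changed probe sets per comparison, 100 at 2-fold and 100 at 4-fold. With noise of 1 pooled SD per probe set, the 4-fold changes were recovered at 98% to 100% in the 10 comparisons. In each, 5 of 5 shifted lists were recovered. The noise was drawn independently for each probe set, so the simulation did not test lists whose genes are correlated. The 2-fold changes were recovered at 68% for MDI in BALB/c mice, 95% in C57BL/6, 96% in B-cell deficient and 74% in crofelemer-treated mice, at 91% and 93% for crofelemer with and without MDI, at 71%, 52% and 88% for the differences by crofelemer, BALB/c strain and B-cell deficiency, and at 95% for the control groups of the B-cell deficient and C57BL/6 mice. False calls numbered 6 to 12 per comparison. A first simulation had given each group its own SD, and its false calls passed the limit of 30 set for the test: 123 for MDI in crofelemer-treated mice, 171 for crofelemer with MDI, 47 for crofelemer with control, and 48 for the difference by crofelemer. The pooled noise was added after that, with the limit kept. MDI in BALB/c mice had 30, and the other 5 comparisons 16 to 24, so false calls were more than with pooled noise in all 10 comparisons.

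The alternatives were quantile normalization over all arrays, centring each array on its median, no intensity trend, array quality weights, a fit of only the groups compared, a filter on probe sets with a mean under 7.09, a 2-fold minimum, the lot as a fixed term or a random block, fits within lots, the replicate number as a block, and leaving out each array in turn. Leaving out 4 narrow arrays of B-cell deficient controls was added after seeing the data. Same-numbered arrays were checked for shared deviations from their group means. The 3 pairs of MDI with crofelemer and MDI alone had correlations of 0.105 to 0.167, which met the rule set in advance for pairing. The mean of the other combinations, -0.0729, adds nothing, since centring a group of 3 arrays fixes it from the pairs. With only 3 pairs, and several comparisons checked, the evidence for pairing is weak. The labels do not say what the numbers mean. In the other comparisons at least 1 pair had a correlation under 0.1.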

Results

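The series holds 51 arrays of mouse lung, of which 49 fall into 8 groups. There were 3 control and 3 MDI arrays from BALB/c mice, 6 control and 13 MDI arrays from C57BL/6 mice, 5 control and 3 MDI arrays from C57BL/6 mice given crofelemer, and 9 control and 7 MDI arrays from B-cell deficient mice. Array means lay between 7.37 and 7.40 in BALB/c, 7.48 and 7.51 in C57BL/6 without crofelemer, 7.43 and 7.48 in C57BL/6 with crofelemer, and 8.02 and 8.07 in B-cell deficient mice. No array of crofelemer-treated mice lay in the range of the C57BL/6 arrays without it. By lot, the C57BL/6 groups had 4, 12, 4 and 3 arrays in lot 1 (control, MDI, control with crofelemer, MDI with crofelemer) and 2, 1, 1 and 0 in lot 3. All 9 B-cell deficient controls were in lot 2, and the 7 MDI arrays of that genotype were split 4 and 3 between lots 1 and 2. All 6 BALB/c arrays were in lot 1.

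**Figure D1:**
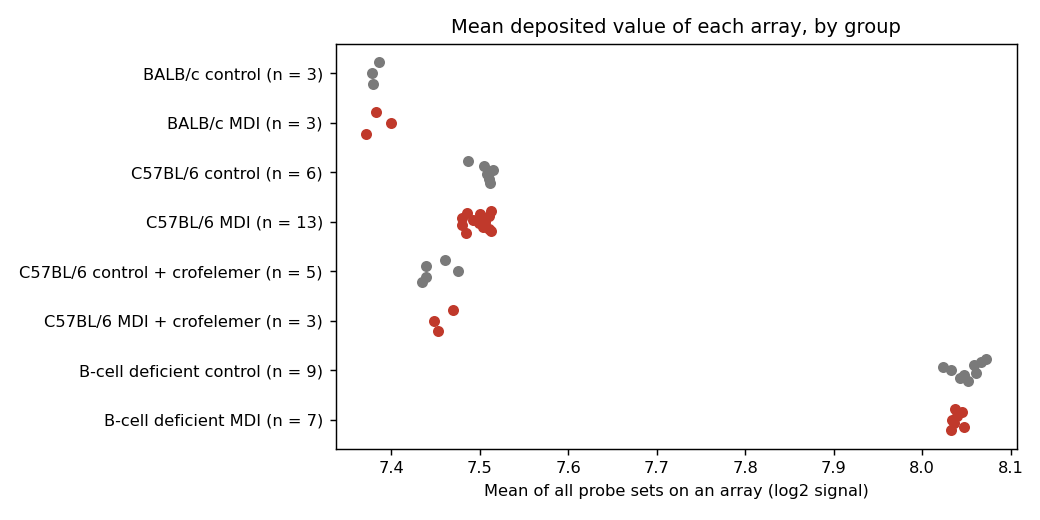
Mean log2 signal of all probe sets on each array (points, 1 per array; horizontal position) by group, grey for control and red for MDI exposure. The B-cell deficient arrays lie between 8.02 and 8.07, above the 3 other sets, and the arrays with crofelemer lie between 7.43 and 7.48.

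In BALB/c mice, the comparison of MDI with control asked how the sensitized lung responds to a respiratory exposure. Clca1, a secreted protein of goblet cells, had the largest rise of the named genes. It rose by 12.52 ± 1.09 (log2, SE; adjusted p = 1.29e-11), from 3.60 ± 1.43 (SD, n = 3) to 16.12 ± 0.14 (n = 3). Control 2 (2.29) stood at the lowest value of its array, so the size is best read as a lower bound. Muc5ac, a gel-forming airway mucin, rose by 5.89 ± 0.64 (adjusted p = 1.07e-08), Fcgbp, a mucus-associated protein, by 4.19 ± 0.47 (adjusted p = 1.68e-08) and Muc5b by 4.08 ± 0.60 (adjusted p = 2.08e-05). The chitinase-like genes Chil4 and Chil3 rose by 5.76 ± 0.53 and 4.41 ± 0.37. Retnla, a product of alternatively activated macrophages and airway epithelium, rose by 5.72 ± 0.64, the chemokine Ccl8 by 5.90 ± 0.62 and the eosinophil-associated ribonuclease Rnase2a by 5.97 ± 0.69.

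Of 22 measured members of the list of mucous metaplasia and secreted airway proteins, 11 rose in BALB/c mice, none fell and 11 did not pass the test (12 rose when adjusted over the list alone). Camera called the list higher (adjusted p = 5.05e-50; 1.40e-06 with an estimated correlation). In all, camera called 16 lists higher and 4 lower in BALB/c mice, and 9 of these 20 held with an estimated correlation. The lower lists are not described here. Of 21 genes of alternatively activated macrophages, 7 rose (12 over the list alone; adjusted p = 0.000287 with an estimated correlation). Of 18 genes of interstitial macrophages and monocytes, 6 rose (10 over the list alone), among them the complement genes C1qa, by 2.18 ± 0.37, and C1qb, by 1.99 ± 0.33, and the list was called with an estimated correlation too (adjusted p = 0.000987). Of 25 chemokines, 4 rose (6 over the list alone; adjusted p = 0.00181 with an estimated correlation), with Ccl12 up by 2.40 ± 0.31. Of 12 MHC class II genes, 1 rose over all probe sets and 9 over the list alone (adjusted p = 0.0107 with an estimated correlation). H2-Eb1 rose by 1.65 ± 0.39 and H2-Aa had a value of 1.15 ± 0.33 (adjusted p = 0.159). Ccl17, a chemokine that attracts T helper 2 cells, had 1.86 ± 0.69 (adjusted p = 0.486), Arg1 0.81 ± 0.74 and the chloride channel gene Cftr 0.09 ± 0.29 (adjusted p = 0.999 for both). Among the 9 genes that fell, Nr4a1, an immediate early transcription factor, fell by 2.79 ± 0.52 and Glp1r, the receptor of glucagon-like peptide 1, fell by 1.71 ± 0.38.

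limma counted 67 changed probe sets in BALB/c mice, 58 higher and 9 lower (1247 at an unadjusted p under 0.05). A simulation at the groups' own spreads gave 30 false calls, beside 200 changed probe sets. The count was 35, 29, 42 and 31 without control 2, control 3, MDI 1 and MDI 2, and 265 with array weights or 269 with BALB/c arrays alone, where Ccl17 (adjusted p = 0.000477) and H2-Aa (0.000225) gained the call. The calls of Nr4a1 (adjusted p = 0.0652 without control 2 and 0.0544 without control 3), Glp1r (adjusted p = 0.0603 without control 2, 0.339 without control 3 and 0.507 without MDI 2) and H2-Eb1 (any of the 6 arrays) ended when these arrays were left out, whereas those of the genes given above from Clca1 to Rnase2a stayed with any 1 array left out.

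In C57BL/6 mice the same comparison again had Clca1 as the named gene with the largest rise. Clca1 rose by 8.12 ± 0.66 (adjusted p = 1.42e-13), from 9.40 ± 2.48 (SD, n = 6) to 17.52 ± 0.78 (n = 13), and the lowest MDI array (16.41) stood above the highest control (13.42). The anion exchanger Slc26a4 rose by 6.24 ± 0.48, Muc5ac by 5.41 ± 0.39, Fcgbp by 4.49 ± 0.28 and Muc5b by 1.95 ± 0.36. Retnla rose by 5.63 ± 0.39, Rnase2a by 5.33 ± 0.42, Ccl8 by 5.09 ± 0.38, the macrophage elastase Mmp12 by 4.95 ± 0.52 and the acidic chitinase Chia1 by 4.85 ± 0.37. Chil4 rose by 3.95 ± 0.32, Arg1 by 2.78 ± 0.45, Ccl17 by 2.70 ± 0.42 and Chil3 by 2.37 ± 0.22, while Cftr had 0.16 ± 0.18 (adjusted p = 0.615).

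Of the 22 mucous genes, 15 rose in C57BL/6 mice and 7 did not pass (17 rose over the list alone; camera adjusted p = 0.000562 with an estimated correlation). Of the 21 genes of alternatively activated macrophages, 16 rose and 2 fell over all probe sets and over the list alone (adjusted p = 0.00287 with an estimated correlation). Of 11 eosinophil genes, 7 rose by either adjustment (adjusted p = 0.0190 with an estimated correlation), among them Alox15, which oxygenates arachidonic acid, by 3.59 ± 0.32, and Ccr3, the eotaxin receptor, by 2.41 ± 0.35. Of 19 type 2 cytokines and their sources, 7 rose and 1 fell (9 and 2 over the list alone; adjusted p = 0.00287 with an estimated correlation), with Il33 up by 1.78 ± 0.25, Ccr8 by 1.42 ± 0.27 and Il4 by 1.20 ± 0.22. Of 18 T-cell genes, 9 rose (11 over the list alone; adjusted p = 0.0256 with an estimated correlation). Of 21 proliferation genes, 19 rose (20 over the list alone), with Mki67 up by 2.19 ± 0.31 and Kif11, a mitotic motor, by 1.60 ± 0.26. That list's call was lost with an estimated correlation (adjusted p = 0.0615).

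Lower lists in C57BL/6 mice included immediate early and heat shock genes, of which 10 of 18 fell (12 over the list alone; adjusted p = 0.0223 with an estimated correlation). Nr4a1 fell by 1.75 ± 0.31, Dusp1 fell by 1.33 ± 0.27 and Fos fell by 1.22 ± 0.27. Of 26 interferon-stimulated genes, 12 fell and 1 rose (17 and 1 over the list alone), with Irf7, a transcription factor of the interferon response, down (it fell by 1.65 ± 0.29) and Oas2 too (it fell by 1.15 ± 0.21). That call was lost with an estimated correlation (adjusted p = 0.10). Of 19 endothelial genes 11 fell, also over the list alone, and of 13 alveolar type 1 genes 9 fell (12 over the list alone), with adjusted p = 0.0657 and 0.0817 with an estimated correlation. Single genes that fell included Cyp2a5, a xenobiotic-metabolizing cytochrome, which fell by 2.51 ± 0.45, Pon1, which fell by 2.08 ± 0.36, and the granulocyte colony-stimulating factor receptor Csf3r, which fell by 1.65 ± 0.40.

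limma counted 3225 changed probe sets in C57BL/6 mice, 1176 higher and 2049 lower (36.5% higher, against 49.4% with arrays centred on their median), and 333 of at least 2-fold, of which 214 were higher and 119 lower. The 16 lot 1 arrays alone gave 2092. No fit was made within lot 3, which holds 2 controls and 1 MDI array, and where Clca1 stood at 17.52 with MDI and at 6.47 and 7.33 in controls.

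**Figure D2:**
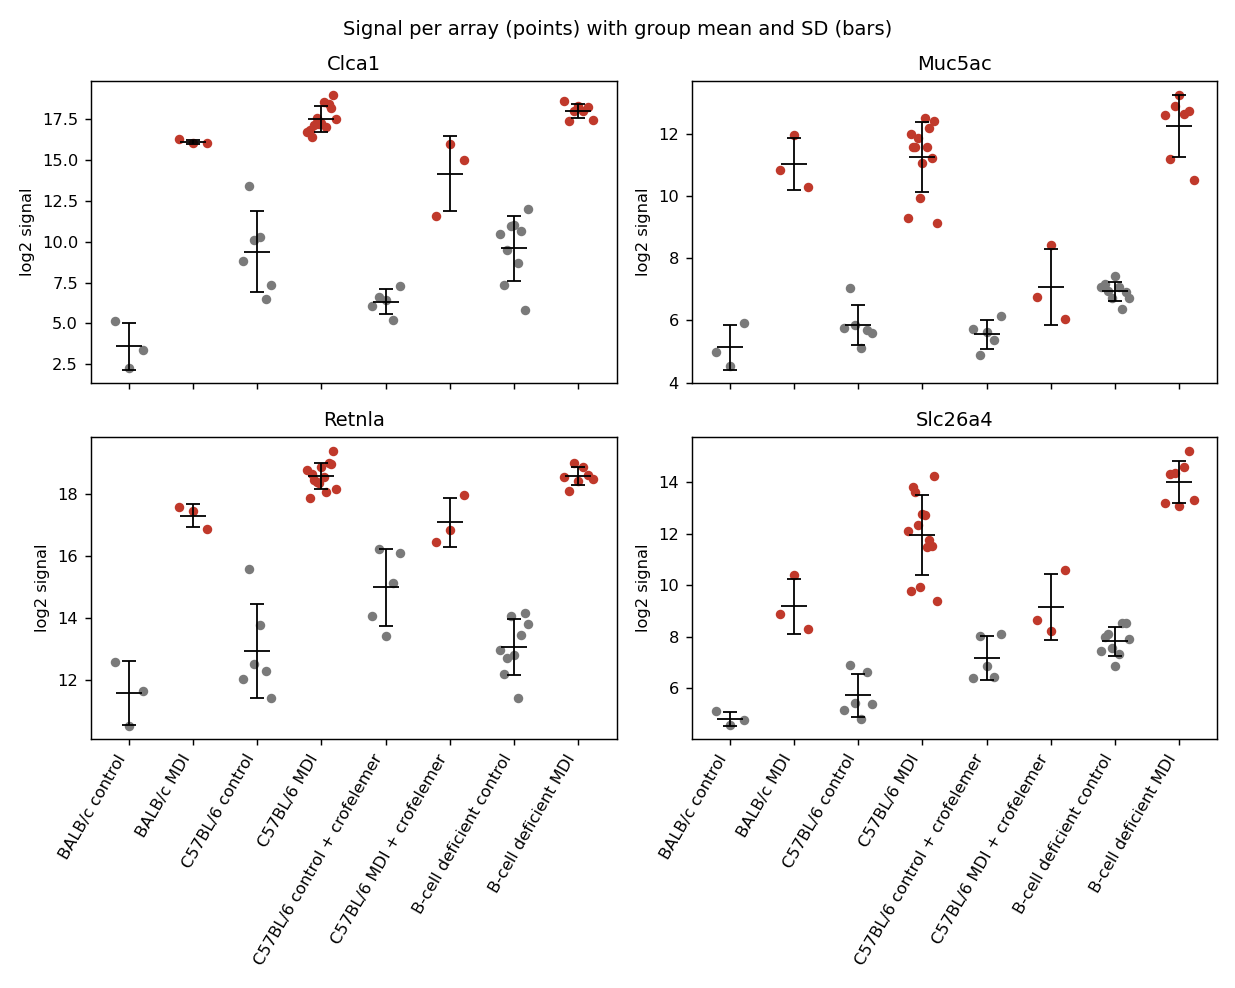
Log2 signal of Clca1, Muc5ac, Retnla and Slc26a4 on each array (points) in the 8 groups, with the group mean and SD (bars); control arrays are grey and MDI arrays red. Clca1 lies between 16.41 and 19.0 in C57BL/6 MDI arrays and between 11.56 and 15.97 in MDI arrays with crofelemer.

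In B-cell deficient mice, MDI was compared with control to see how the response runs without mature B cells. Clca1 rose by 8.41 ± 0.67 (adjusted p = 8.09e-14), from 9.61 ± 1.99 (SD, n = 9) to 18.01 ± 0.44 (n = 7). Rnase2a rose by 7.56 ± 0.43, Slc26a4 by 6.19 ± 0.49, Mmp12 by 6.10 ± 0.53, Retnla by 5.51 ± 0.40, Muc5ac by 5.32 ± 0.40, Ccl8 by 4.92 ± 0.38 and Chia1 by 4.88 ± 0.37. Fcgbp rose by 4.36 ± 0.29, Chil4 by 3.57 ± 0.32, Arg1 by 3.44 ± 0.46, Ccl17 by 3.33 ± 0.42, Muc5b by 2.48 ± 0.37 and Chil3 by 2.15 ± 0.23. Cftr had 0.42 ± 0.18 (adjusted p = 0.0598), and the B-cell genes Ms4a1 and Cd79a had -0.43 ± 0.21 and -0.31 ± 0.23 (adjusted p = 0.101 and 0.285).

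Of the 22 mucous genes, 17 rose in B-cell deficient mice by either adjustment, and of the 21 genes of alternatively activated macrophages 17 rose (18 over the list alone; adjusted p = 0.0109 with an estimated correlation for both lists). Of 11 eosinophil genes, 9 rose by either adjustment (adjusted p = 0.0120 with an estimated correlation), with Alox15 up by 4.66 ± 0.33 and Ccr3 by 3.67 ± 0.36. Of 18 T-cell genes 15 rose by either adjustment, of 19 dendritic cell genes 14 (15 over the list alone), and of 12 MHC class II genes 10 by either adjustment, among them H2-Eb1 by 1.95 ± 0.24 and the lysosomal protease Ctss by 1.93 ± 0.22 (adjusted p = 0.0109, 0.0133 and 0.0323 with an estimated correlation). Of 18 genes of interstitial macrophages and monocytes, 13 rose and 1 fell (14 and 2 over the list alone; adjusted p = 0.0159 with an estimated correlation), including C1qc, C1qb and C1qa by 2.46 ± 0.26, 2.40 ± 0.20 and 2.29 ± 0.23. Of 19 type 2 cytokines and their sources, 8 rose and 2 fell by either adjustment (adjusted p = 0.0400 with an estimated correlation). Of 21 proliferation genes, 20 rose by either adjustment, with Mki67 up by 2.01 ± 0.31 (adjusted p = 0.145 for the list with an estimated correlation). Of 26 interferon-stimulated genes, 9 rose and 1 fell by either adjustment, with Irf7 up by 1.75 ± 0.30 and Mx1 by 1.09 ± 0.19 (adjusted p = 0.331 for the list with an estimated correlation).

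Genes that fell in B-cell deficient mice included Vipr2, a receptor of vasoactive intestinal peptide, which fell by 1.88 ± 0.19, the sulfotransferase Sult1d1, which fell by 2.14 ± 0.32, Pon1, which fell by 1.97 ± 0.37, and Cyp2a5, which fell by 2.01 ± 0.46. The keratins Krt13 and Krt4, of stratified squamous epithelium, fell by 2.58 ± 0.64 and fell by 2.56 ± 0.72. Control 7 stood far above the other controls for both (14.21), and without it they fell by 1.84 and fell by 1.75. Within lot 2 the call of Krt4 ended (adjusted p = 0.0705). limma counted 8205 changed probe sets, 3604 higher and 4601 lower. The split turned with brightness, with 2798 higher and 1443 lower among bright probe sets, 806 higher and 3158 lower among dim ones, and 3130 higher and 1926 lower with the dim ones filtered out. It also turned at a 2-fold minimum (641 higher, 186 lower) and within lot 2 (2268 higher, 2090 lower). Centring the arrays on their median moved the median of all probe sets to -0.11. The count was 3780 without 4 control arrays with a narrow spread of values, 4499 with the lot as a fixed term and 4358 within lot 2. Without those 4 arrays the 17, 17, 9, 20 and 10 genes that rose in the mucous, alternatively activated macrophage, eosinophil, proliferation and MHC class II lists numbered 15, 17, 8, 17 and 10.

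The 3 responses to MDI were set side by side over all probe sets, which are not independent replicates. The Pearson correlation of log2 fold changes was 0.49 for BALB/c with C57BL/6, 0.446 for BALB/c with B-cell deficient and 0.452 for C57BL/6 with B-cell deficient mice (Spearman's rho 0.243, 0.245 and 0.153). Over the 11103 bright probe sets it was 0.583, 0.574 and 0.657 (rho 0.312, 0.398 and 0.456). Of 58 probe sets higher in BALB/c, 42 were also higher in C57BL/6, where chance gives 3.07, and 50 in B-cell deficient mice, where chance gives 9.41. C57BL/6 and B-cell deficient mice shared 732 higher probe sets (191 by chance) and 647 lower ones (425 by chance), and 166 went opposite ways. Among bright probe sets they shared 550 higher (188 by chance) and 569 lower ones (223 by chance).

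**Figure D3:**
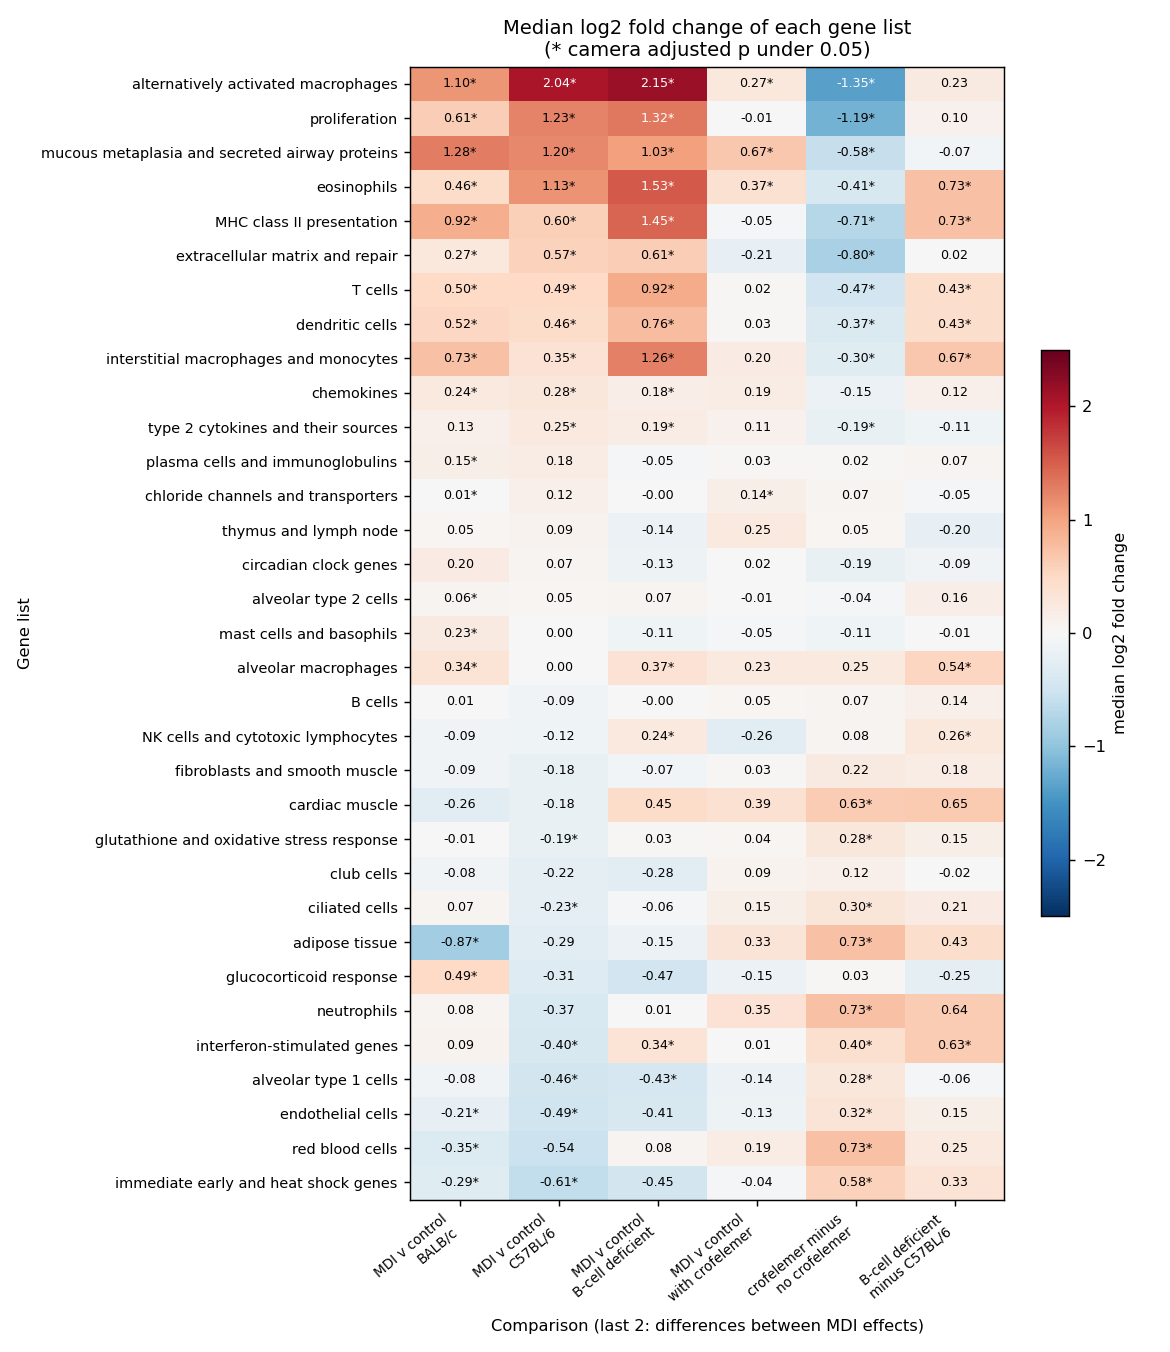
Median log2 fold change of each of the 33 gene lists (lines) in 6 comparisons (columns), the last 2 being differences between MDI effects; colour gives the same value, and asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation. The median of alternatively activated macrophage genes is 2.15 in B-cell deficient, 2.04 in C57BL/6, 1.10 in BALB/c and 0.27 in crofelemer-treated mice.

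The effect of MDI in BALB/c minus that in C57BL/6 mice was tested directly. Hal, the histidine-degrading enzyme histidase, had a difference of 2.27 ± 0.28 (adjusted p = 1.76e-06) and Ubxn6 1.13 ± 0.22 (adjusted p = 0.0241). The phospholipase Pla2g4c had -3.67 ± 0.52 (adjusted p = 5.00e-05) and G0s2, an inhibitor of fat breakdown, -1.43 ± 0.28 (adjusted p = 0.0238). The airway genes had 4.40 ± 1.27 for Clca1 (adjusted p = 0.272; it includes the BALB/c controls near the low end of the scale), 2.13 ± 0.70 for Muc5b (0.371), 2.05 ± 0.43 for Chil3 (0.0516), 1.81 ± 0.61 for Chil4 (0.386), 0.48 ± 0.75 for Muc5ac (0.932), 0.08 ± 0.75 for Retnla (0.994), -0.07 ± 0.34 for Cftr (0.982), -0.84 ± 0.80 for Ccl17 (0.876) and -1.96 ± 0.87 for Arg1 (0.553). Chil3 gained the call with quantile normalization (adjusted p = 0.00193), the filter on dim probe sets (0.0328) and array weights (0.00294), and Clca1 with array weights (0.0453) and within lot 1 (0.0144). limma counted 6 probe sets (1737 at an unadjusted p under 0.05), and camera called 10 lists, of which 0 held with an estimated correlation. The count was 3 without BALB/c control 3, MDI 1 or MDI 3 or without C57BL/6 control 3, 10 without C57BL/6 control 6, and 183 with array weights. Hal and Pla2g4c kept their calls with any 1 array left out, while those of Ubxn6 and G0s2 ended without 8 and 4 single arrays. Hal lost its call with the replicate block over 12 arrays (adjusted p = 0.128), as did Ubxn6 (0.394) and G0s2 (0.638).

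The effect of MDI in B-cell deficient minus that in C57BL/6 mice asked whether the missing B cells alter the response. Interferon-stimulated genes stood out. Of 26, 15 had a higher effect in B-cell deficient mice and 0 a lower one (19 over the list alone), with a median difference of 0.63 and adjusted p = 0.266 with an estimated correlation. Irf7 had a difference of 3.40 ± 0.42 (adjusted p = 2.64e-06), Ifi27l2a 2.11 ± 0.40, Oas2 1.54 ± 0.30 and Usp18 1.09 ± 0.20. The largest differences included genes of neutrophils and other phagocytes, with Mmp9 at 3.42 ± 0.60, Tarm1 at 2.68 ± 0.57, Retnlg at 2.59 ± 0.57 and Il1b at 2.27 ± 0.52, but the neutrophil list as a whole was not called (4 of 19 higher and 1 lower; 5 and 1 over the list alone; adjusted p = 0.197). Retnlg rose from 12.87 ± 1.04 (SD, n = 9) to 16.72 ± 0.41 (n = 7) in B-cell deficient mice, whereas Mmp9 went from 5.75 to 7.55 there and from 8.91 to 7.29 in C57BL/6 mice, and Csf3r from 7.76 to 8.21 and from 12.73 to 11.08. Lower effects were found for Sprr1a (-2.11 ± 0.40), Ccdc7a (-1.98 ± 0.32) and Styk1 (-1.74 ± 0.34). Krt13 had -2.53 ± 0.89 and Krt4 -2.80 ± 1.00, against -1.79 and -1.99 without control 7, and their calls ended without 9 and 13 other single arrays. The airway genes had differences of 0.28 ± 0.94 for Clca1, -0.09 ± 0.56 for Muc5ac, 0.52 ± 0.52 for Muc5b, -0.12 ± 0.55 for Retnla, -0.21 ± 0.32 for Chil3, -0.39 ± 0.45 for Chil4, 0.66 ± 0.64 for Arg1, 0.62 ± 0.59 for Ccl17 and 0.26 ± 0.25 for Cftr, with adjusted p from 0.471 to 0.926, which does not show that they were equal.

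limma counted 4502 probe sets for this difference, 2059 higher and 2443 lower (45.7% higher, against 28.5% with arrays centred on their median, which put the median of all probe sets at -0.11). The split turned with brightness, with 1679 higher and 321 lower among bright probe sets and 380 higher and 2122 lower among dim ones, and with the dim ones filtered out 1768 were higher and 598 lower (363 and 269 at a 2-fold minimum). Camera called 8 lists, of which 0 held with an estimated correlation. The count was 719 without the 4 narrow control arrays and 2444 with the lot as a term. Without those arrays 7 of the 26 interferon-stimulated genes were called, with a median of 0.62 (13 with the lot as a term, median 0.72), and the calls of Il1b (1.71, adjusted p = 0.0652), Rnase2a (2.06, 0.0721), Csf3r (1.52, 0.144), Stfa1 (-0.56, 0.103), Tgm3 (-1.84, 0.0669), Rptn (-2.36, 0.0747), Krt13 (-3.00, 0.0721) and Krt4 (-3.26, 0.0827) ended. Those of Csf3r (0.0699), Tgm3 (0.0620), Rptn (0.0590), Krt13 (0.0748) and Krt4 (0.0876) also ended with the lot as a term.

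B-cell deficient controls were compared with C57BL/6 controls to see the effect of the genotype without MDI. B-cell genes were far lower. Jchain, the joining chain of polymeric immunoglobulin, fell by 6.17 ± 0.40 (adjusted p = 2.88e-18), from 9.24 ± 1.25 (SD, n = 6) to 3.07 ± 0.40 (n = 9), where control 8 (2.65) stood at the lowest value of its array, so the size is best read as a lower bound. The B-cell receptor component Cd79a fell by 5.83 ± 0.24. Bank1 fell by 4.45 ± 0.32, Cd22 fell by 2.73 ± 0.18, Cd79b fell by 2.67 ± 0.21 and Ms4a1 fell by 2.54 ± 0.22. Of 20 B-cell genes, 18 fell by either adjustment (adjusted p = 0.000213 with an estimated correlation). Of 16 alveolar type 2 genes 10 fell and 2 rose, and of 10 genes of plasma cells and immunoglobulins 5 fell and 4 rose, both by either adjustment (adjusted p = 0.0371 and 0.00475 with an estimated correlation). Neutrophil genes were lower too, with 10 of 19 down and 4 up by either adjustment (adjusted p = 0.139 with an estimated correlation). Csf3r fell by 4.97 ± 0.43, S100a8 fell by 3.97 ± 0.63, Ngp fell by 3.80 ± 0.39, Il1b fell by 3.44 ± 0.39 and Cxcr2 fell by 3.33 ± 0.39. Higher genes included Plac9b (3.41 ± 0.17), Plac9a (3.30 ± 0.18), Zbtb16 (3.07 ± 0.46) and the defensin Defb1 (2.93 ± 0.19). Krt4 had 3.26 ± 0.75 and Krt13 3.22 ± 0.67, against 2.44 and 2.48 without control 7.

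Genotype and any separate processing could not be separated in B-cell deficient control against C57BL/6 control. No lot holds controls of both, but B-cell deficient MDI arrays bridge the lots, and with the lot as a term 11056 probe sets were called (10324 higher, 732 lower). limma counted 15822 changed probe sets, of which 14308 were higher (90.4%), and the median of all probe sets was shifted by 0.54. Quantile normalization brought that median to 0.00 and the share of higher calls to 50.5% (48.4% with median centring). The falls of B-cell genes run against the shift. Camera called 15 lists lower, 7 of them with a positive median.

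Crofelemer-treated C57BL/6 mice were compared with and without MDI to see which part of the response remains under the drug. Clca1 rose by 7.86 ± 0.97 (adjusted p = 2.77e-06), from 6.31 ± 0.77 (SD, n = 5) to 14.18 ± 2.32 (n = 3), with the lowest MDI array at 11.56 and the highest control at 7.30. Fcgbp rose by 2.20 ± 0.42 (adjusted p = 0.0128) and Pigr, the epithelial transporter of polymeric immunoglobulin, by 1.52 ± 0.33 (adjusted p = 0.0498). The other airway genes had 2.09 ± 0.57 for Retnla (adjusted p = 0.186), 1.73 ± 0.47 for Chil4 (0.183), 1.52 ± 0.58 for Muc5ac (0.428), 1.03 ± 0.54 for Muc5b (0.640), 0.94 ± 0.66 for Arg1 (0.770), 0.85 ± 0.33 for Chil3 (0.451), 0.26 ± 0.26 for Cftr (0.876) and -0.26 ± 0.61 for Ccl17 (0.962). Over the 6 arrays with shared numbers, which did not meet the rule for pairing here, Retnla and Chil4 gained the call with the replicate block (adjusted p = 0.00141 and 0.000367). Of 22 mucous genes 3 rose (8 rose and 1 fell over the list alone), with adjusted p = 0.154 for the list with an estimated correlation. Camera called 4 lists at the preset correlation and 0 of them held. Other changed genes were Cep72, Dbpht2 and Tchh (higher) and Ccdc25, Psip1 and Tsnaxip1 (lower).

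limma counted 12 probe sets, 8 higher and 4 lower (1826 at an unadjusted p under 0.05), and the share of higher calls, 66.7%, was 45.5% of 22 calls after quantile normalization. The count was 4, 1 and 1 without MDI array 1, 2 or 3, 6 and 7 without control 3 or 4, 5 with array weights and 2 within lot 1. Clca1 kept its call with any 1 array left out, Fcgbp lost it without MDI 2 (adjusted p = 0.192) or MDI 3 (adjusted p = 0.0593) and within lot 1 (adjusted p = 0.0534), and Pigr lost it without 7 of the 8 arrays. Each of the 6 other genes named lost its call without at least 2 of the arrays. A simulation at the groups' own spreads gave 123 false calls. It held 200 changed probe sets, so that number cannot be set against the 12 counted.

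The difference between the effects of MDI with and without crofelemer was tested directly. Muc5ac had a smaller effect under crofelemer, by -3.88 ± 0.69 (adjusted p = 0.00397), and so had Rnase2a (-3.97 ± 0.75), Slc26a4 (-4.26 ± 0.87), Retnla (-3.54 ± 0.69), Mmp12 (-3.87 ± 0.92), Chia1 (-3.47 ± 0.65), Ccl8 (-3.16 ± 0.67) and Alox15 (-2.54 ± 0.57). Higher controls with crofelemer than without made up part of the difference for Retnla (14.98 and 12.93), Slc26a4 (7.18 and 5.72) and Ccl8 (7.35 and 6.30). The MDI arrays stood at 17.08 with crofelemer and 18.57 without for Retnla. Controls were not higher with crofelemer for Muc5ac (5.55 and 5.84) and Rnase2a (4.69 and 5.88). Clca1 had -0.26 ± 1.17 (adjusted p = 0.960), a wide error. Values that did not pass were -2.96 ± 0.74 for Ccl17 (adjusted p = 0.0506), -2.23 ± 0.57 for Chil4 (0.0576), -1.51 ± 0.40 for Chil3 (0.0693), -1.83 ± 0.80 for Arg1 (0.328), -0.92 ± 0.65 for Muc5b (0.599) and 0.10 ± 0.31 for Cftr (0.942). Ccl17, Chil4 and Chil3 gained the call with quantile normalization (adjusted p = 0.0493, 0.0493 and 0.0499) and with arrays centred on their median (0.0417, 0.0417 and 0.0458). Igfbp3, a binding protein of insulin-like growth factors, had 2.48 ± 0.35 (adjusted p = 9.77e-05). Of 21 genes of alternatively activated macrophages 4 had a smaller effect over all probe sets (13 smaller and 1 larger over the list alone), and of 21 proliferation genes 1 (13 over the list alone), with adjusted p = 0.0740 and 0.165 with an estimated correlation. Most proliferation genes were already higher with crofelemer in control mice, as given below. Camera called 20 lists and 0 held with an estimated correlation.

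limma counted 94 probe sets for this difference, 40 higher and 54 lower (42.6% higher, against 25.7% with arrays centred on their median). The count was 36 and 20 without MDI with crofelemer 1 or 2, 42 and 57 without control with crofelemer 2 or 4, 40, 58 and 62 without C57BL/6 control 1, 4 or 5, 10 with only the 4 groups in the fit and 8 within lot 1. Muc5ac, Rnase2a and Igfbp3 kept their calls with any 1 array left out but lost them with the replicate block (adjusted p = 0.383, 0.187 and 0.152), which keeps 12 arrays and gave 4 calls with or without the number, and Rnase2a also with only the 4 groups in the fit (0.0577). The calls of Chia1 (0.0627), Slc26a4 (0.0831), Retnla (0.05001), Ccl8 (0.115), Mmp12 (0.134) and Alox15 (0.0819) ended with only the 4 groups in the fit too, and likewise within lot 1 (adjusted p from 0.0551 to 0.0928) and with the replicate block (0.383 to 0.647). Chia1 lost it without MDI with crofelemer 1 (adjusted p = 0.0641), and the calls of Slc26a4, Retnla and Ccl8 ended without MDI with crofelemer 1 and without 2, as did those of Mmp12 and Alox15, which also ended without other arrays.

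A reference set of the 51 genes raised at least 2-fold in BALB/c mice was formed after the data were seen. It was checked on mice that share no array with the BALB/c fold changes. The fit that chose the genes pooled the variance over all groups, so the check is not fully independent. The set's median log2 fold change was 2.18 in BALB/c, where it was chosen, and 1.37 in C57BL/6 (40 rose). It was 1.95 in B-cell deficient (46 rose) and 0.44 in crofelemer-treated mice (3 rose). The difference between the effects with and without crofelemer had a median of -0.99, with 11 genes past the test and a camera p = 0.000604 with an estimated correlation. For B-cell deficient minus C57BL/6 mice the median difference was 0.32, with 8 genes past the test and a camera p = 0.329 with an estimated correlation. The mean of the set per array still differed between MDI and control under crofelemer, by 0.79, from 9.13 ± 0.18 (SD, n = 5) to 9.92 ± 0.30 (n = 3), with p = 0.0179 in a 2-sided exact permutation test of the 56 splits, the smallest p it can give.

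**Figure D4:**
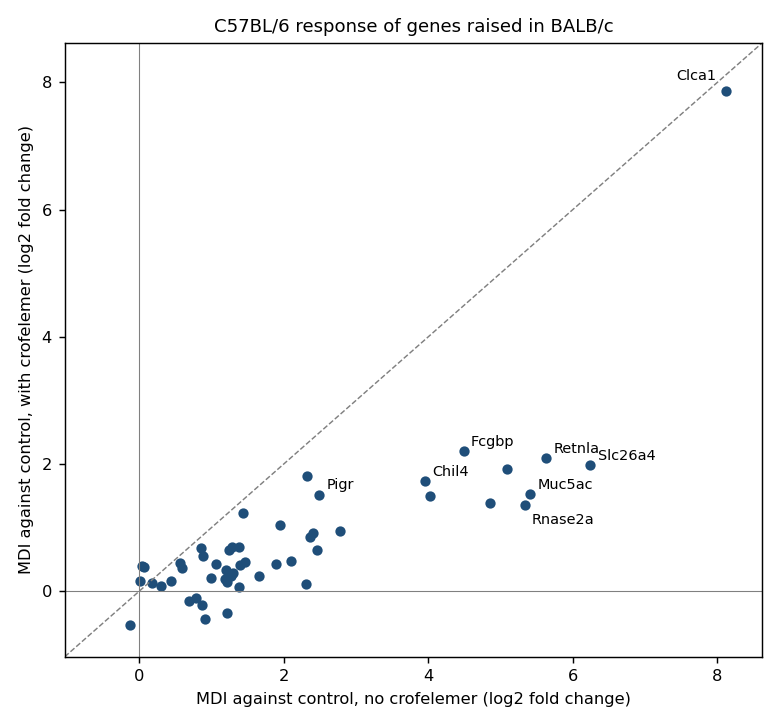
Log2 fold change after MDI with crofelemer (vertical) against without crofelemer (horizontal) in C57BL/6 mice, 1 point per gene of the 51 raised in BALB/c mice; the broken line marks equal values. Clca1 lies near that line at 8.12 and 7.86, and Muc5ac lies below it at 5.41 and 1.52.

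Crofelemer-treated MDI mice were also compared with MDI mice without the drug. In C57BL/6 mice the array means with crofelemer all lie below those without it, so the drug and any separate processing cannot be told apart. Rnase2a fell by 5.16 ± 0.54, Muc5ac fell by 4.18 ± 0.50, Chia1 fell by 3.48 ± 0.48, Ccl17 fell by 3.44 ± 0.54, Chil4 fell by 2.59 ± 0.41, Chil3 fell by 1.90 ± 0.29, Clca1 fell by 3.35 ± 0.85 and Retnla fell by 1.49 ± 0.50. Muc5b had -0.29 ± 0.47 (adjusted p = 0.687), Cftr -0.18 ± 0.23 (0.589) and Arg1 -1.10 ± 0.58 (0.145). Over the 6 arrays of the 3 same-numbered pairs, which keep 3 of the 13 MDI arrays, Arg1 fell by 1.90 with the replicate block (adjusted p = 0.00604). That block assumes a pairing for which the evidence is weak. The matrix glycoprotein Tnc was higher by 4.32 ± 0.43 and the transmembrane glycoprotein Gpnmb by 3.89 ± 0.32, as were the histone genes H2bc18 (3.72 ± 0.46), H1f1 (3.59 ± 0.44) and H2ac15 (3.44 ± 0.45). Of 20 B-cell genes 19 fell by either adjustment, with Cd79a down (it fell by 2.63 ± 0.29), and of 16 ciliated cell genes 12 fell (13 fell and 1 rose over the list alone), with Sntn down (it fell by 2.46 ± 0.25). The adjusted p with an estimated correlation was 0.134 and 0.248. limma counted 7232 probe sets, 3336 higher and 3896 lower (46.1% higher, against 59.4% with arrays centred on their median, which put the median of all probe sets at 0.14; 476 higher and 1518 lower at a 2-fold minimum), and with the replicate block on the 3 pairs 2148, where the same 6 arrays without the block gave 1599. Camera called 15 lists, and 0 held with an estimated correlation. A simulation at the groups' own spreads gave 171 false calls, beside 200 changed probe sets. Clca1 lost its call without MDI with crofelemer 1 (it fell by 2.04, adjusted p = 0.126), and Retnla without MDI with crofelemer 1 or 2 (adjusted p = 0.158 and 0.0826).

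In control mice, crofelemer was compared with no crofelemer under the same limit. Tnc was higher by 5.79 ± 0.41, and the histone genes H2ac15, H1f1 and H3c6 by 5.65 ± 0.42, 5.28 ± 0.42 and 5.14 ± 0.33. Of 21 proliferation genes 20 rose by either adjustment, with Plk1, a mitotic kinase, up by 3.95 ± 0.44, and of 18 genes of extracellular matrix and repair 16 rose and 1 fell by either adjustment, with Col3a1 up by 2.71 ± 0.26 and Postn down (it fell by 2.51 ± 0.20). The adjusted p with an estimated correlation was 0.214 for both. All 20 B-cell genes fell, Cd79a among them (it fell by 2.80 ± 0.27), and 14 of 16 ciliated cell genes fell (15 over the list alone), Dynlrb2 among them (it fell by 2.80 ± 0.20), with adjusted p = 0.0973 and 0.120 with an estimated correlation. Bpifa1, a secreted airway protein, fell by 4.44 ± 0.92, and Cyp1a1 fell by 4.20 ± 0.59. Of the airway genes, Clca1 fell by 3.09 ± 0.81 and Retnla was higher by 2.05 ± 0.48, though Retnla had 1.24 (adjusted p = 0.0607) within lot 1. Arg1 (0.73 ± 0.55), Muc5b (0.63 ± 0.45), Cftr (-0.28 ± 0.22), Muc5ac (-0.29 ± 0.48), Chil4 (-0.36 ± 0.39), Chil3 (-0.38 ± 0.27) and Ccl17 (-0.48 ± 0.51) did not pass, with adjusted p from 0.269 to 0.665. limma counted 8669 probe sets, 3916 higher and 4753 lower (45.2% higher, against 64.8% with arrays centred on their median, which put the median of all probe sets at 0.19; 614 higher and 1705 lower at a 2-fold minimum). Camera called 9 lists, and 0 held with an estimated correlation. Within lot 1 the count was 7185.

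Both crofelemer comparisons, which share no array, had a correlation of 0.833 across probe sets. They shared 2009 higher probe sets (588 by chance) and 3145 lower ones (834 by chance). Of 5173 called in both, 5154 went the same way.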

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

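The tests of the lot and of the narrow control arrays for interferon-stimulated genes were chosen only after the results were seen, and the squamous marker list was written after Krt13 and Krt4 stood out but before its other values were seen.

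In 588 tests of single arrays, over 147 genes in the 4 groups of 4 to 10 arrays, 30 values, on 10 arrays, lay farther from the rest of their group than the 95% limit of Dixon's test, where chance alone gives 29.4. The number by itself is thus what chance gives. Many of the genes were named for large changes in these same data, and genes that move together give outliers on the same array. The gathering of values on few arrays was thus favoured by the choice of genes and is not independent evidence.

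Of these outlying values, 12 fell on squamous and muscle genes in a pair of B-cell deficient arrays. Control 7 was the highest of 9 controls for Krt13 (14.21), Krt4 (14.21), Rptn (12.38), Ly6g6c (11.56), Tgm3 (11.07) and the muscle gene Tnni2 (10.27), and MDI 3 the highest of 7 for Krt13 (9.23), Krt4 (8.77), Rptn (8.49), Ly6g6c (8.36), Tgm3 (7.84) and Tnni2 (7.95). A candidate explanation for control 7 is stratified squamous epithelium, as from the oesophagus, carried along with the lung. Of 19 listed markers of that tissue 17 were measured, and their median was 1.38 above the mean of the other 8 controls, with 11 at least 1 higher and 0 of 10000 random lists as high. Sprr3 stood 5.51 and Krtdap 3.83 above, while Evpl had -0.18. MDI 3 was not tested against the list, and no biological explanation was tested.

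Other arrays apart from their group were, among C57BL/6 controls, control 1 for Defb1 (5.54), Styk1 (8.09) and Tubb1 (8.89), control 2 for H1f1 (6.46), H2ac12 (12.19) and, as the lowest, Grtp1 (7.44), and control 6 for Ccdc7a (7.42) and, as the lowest, Cd79b (8.30). Among controls with crofelemer they were control 5 for Ccl24 (5.02) and Chia1 (8.62) and control 3 for Grtp1 (5.80). In B-cell deficient mice they were control 7 for Ccdc153 (10.75), control 8 for Mcm5 (6.94), Oas2 (6.10), Rnase2a (8.34) and, as the lowest, Fcgbp (7.85), MDI 5 for Ccdc25 (8.71) and, as the lowest, MDI 4 for Cr2 (4.37).

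Of 26 interferon-stimulated genes, 12 fell and 1 rose after MDI in C57BL/6 mice (median -0.40), while 9 rose and 1 fell in B-cell deficient mice (median 0.34), and both list calls were lost with an estimated correlation (adjusted p = 0.10 and 0.331). The tested difference had a median of 0.63, with Irf7 at 3.40, Ifi27l2a at 2.11, Oas2 at 1.54 and Usp18 at 1.09. With the lot as a term the median was 0.72, and without the 4 narrow control arrays 0.62. Without any 2 of the 6 C57BL/6 controls it was at least 0.49 (15 pairs). None of these 3 thus accounts for most of the median difference, but a part played by each is not excluded. Fewer members were called without the narrow arrays, as given above. The absence of B cells may underlie the difference, a hypothesis found and tested on the same data. With an estimated correlation the list's adjusted p was 0.266.

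Other effects of MDI that differed between B-cell deficient and C57BL/6 mice by a test of the difference (4502 probe sets) were those on Mmp9 (3.42), Tarm1 (2.68), Retnlg (2.59), Slc2a3 (2.28), Il1b (2.27), Rnase2a (2.22), Rac2 (2.17), Csf3r (2.10), Stfa1 (-0.84), Tgm3 (-1.73), Styk1 (-1.74), Ly6g6c (-1.79), Ccdc7a (-1.98), Sprr1a (-2.11), Rptn (-2.20), Krt13 (-2.53) and Krt4 (-2.80). Of 100 splits of the MDI labels, 1, the real one, gave as many calls (highest other 553). These splits also break the effect of MDI itself, so they cannot decide whether the effects differ by more than chance. Without the 4 narrow control arrays the calls of Il1b, Rnase2a, Csf3r, Stfa1, Tgm3, Rptn, Krt13 and Krt4 ended, and with the lot as a term those of Csf3r, Tgm3, Rptn, Krt13 and Krt4. Without those arrays the differences of Krt13 (-3.00), Krt4 (-3.26), Rptn (-2.36) and Tgm3 (-1.84) were larger in size. Control 7, the highest control for these genes, weighs more among fewer controls, so this does not decide whether the narrow arrays added to the differences. Those of Il1b (1.71), Csf3r (1.52), Stfa1 (-0.56) and Rnase2a (2.06) were smaller.

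Between BALB/c and C57BL/6 mice the effect of MDI differed for 6 probe sets, with Hal at 2.27, Ubxn6 at 1.13, G0s2 at -1.43 and Pla2g4c at -3.67. Of 100 splits of the MDI labels, 4 gave as many, the real one included (highest other 12), a share under 0.05. As above, these splits break the effect of MDI itself and do not test whether the effects are equal. Simulated data gave 11 false calls with pooled noise and 17 with each group's own SD. The simulations held 200 changed probe sets, so these numbers cannot be set against the 6 counted. Leaving out BALB/c control 3 gave 3, so the count carries little weight.

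Between C57BL/6 mice with and without crofelemer the effect of MDI differed for 94 probe sets. Of 100 splits of the MDI labels, 5 gave as many, the real one included (highest other 613), so chance cannot be excluded for the count. Why a split gave several times the real count was not tested, and these splits also break the effect of MDI itself. The genes were Igfbp3 (2.48), Cyp2a4 (2.13), Gsta2 (1.82), Tubb1 (1.54), Slc16a3 (1.46), Colgalt2 (1.41), Grtp1 (1.39), Faim2 (1.32), Mki67 (-2.33), Alox15 (-2.54), Pla2g4c (-2.62), Ccl8 (-3.16), Chia1 (-3.47), Retnla (-3.54), Mmp12 (-3.87), Muc5ac (-3.88), Rnase2a (-3.97) and Slc26a4 (-4.26), and the list medians were -1.35 for alternatively activated macrophages and -1.19 for proliferation, whose calls were lost with an estimated correlation (adjusted p = 0.0740 and 0.165). Few of the gene calls are firm. With each array left out in turn, the call ended without 19 single arrays for Colgalt2, 17 for Faim2, 9 for Mki67, 8 for Mmp12, 7 for Cyp2a4, 6 for Gsta2, 6 for Grtp1, 5 for Tubb1, 4 for Alox15, 2 each for Slc16a3, Ccl8, Retnla and Slc26a4, and 1 each for Chia1 and Pla2g4c. With only the 4 groups in the fit all calls but those of Igfbp3, Muc5ac and Pla2g4c ended. With the replicate block, which keeps 12 arrays, all 18 ended, though each gene kept its direction.

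In the 2 arrays that belong to no group, Clca1 stood at 15.94 and 19.24, above the highest C57BL/6 control (13.42).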

How the results depend on the processing

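Leaving out the 4 narrow arrays was chosen only after the data were seen; all other alternatives were planned.

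Counts moved by more than 1.5 times as follows, and the cause was not tested unless given. A 2-fold minimum, which asks for more, left 333 for MDI in C57BL/6, 827 in B-cell deficient and 6 in crofelemer-treated mice, 1994 and 2319 for crofelemer with MDI and with control, 632 for the difference by B-cell deficiency and 5163 for the controls of both genotypes. Array weights gave 265 for MDI in BALB/c, 5 in crofelemer-treated mice, 53 for the difference by crofelemer and 183 for that by BALB/c strain. A fit of the compared groups alone gave 269 for MDI in BALB/c, 10 for the difference by crofelemer and 2 for that by strain. The filter on dim probe sets, which tests fewer, gave 5056 for MDI in B-cell deficient and 4 in crofelemer-treated mice, 2366 for the difference by B-cell deficiency and 7188 for the controls of both genotypes. Quantile normalization gave 22 for MDI in crofelemer-treated mice. The lot as a fixed term gave 4499 for MDI in B-cell deficient mice and 2444 for their difference from C57BL/6. Fewer arrays, within lot 1, gave 2092 for MDI in C57BL/6, 2 in crofelemer-treated mice and 8 for the difference by crofelemer, and within lot 2 4358 for MDI in B-cell deficient mice. Leaving out the intensity trend, centring the arrays, or the lot as a random block moved no count.

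Without the 4 narrow arrays MDI in B-cell deficient mice gave 3780 and its difference from C57BL/6 719. The arrays had SDs of 2.85 to 2.96, against 3.03 for the next. Of 100 draws of 4 controls left out, 1, these 4, left as few lower dim probe sets (905 of 3158, lowest other 1110, median 2278), so narrow arrays may account for many of them. The 4 arrays also had higher lower quartiles (5.66 to 5.81) than the other controls (5.50 to 5.55). Choosing them by a narrow spread thus favoured few lower dim calls in advance, so the rank among draws is weak evidence. The count of all probe sets without these arrays had been seen before this test.

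The replicate block gave 283 for MDI in BALB/c, 930 in C57BL/6, 2148 for crofelemer with MDI, 4 for the difference by crofelemer and 2 for that by strain. The same arrays without the number gave 269, 786, 1599, 4 and 1, so most of the move comes from fewer arrays or groups.

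With each array left out in turn, counts ran from 29 to 67 for MDI in BALB/c, 2278 to 3489 in C57BL/6, 7074 to 8558 in B-cell deficient and 1 to 13 in crofelemer-treated mice, 4993 to 7786 and 7803 to 8512 for crofelemer with MDI and with control, 20 to 125 for the difference by crofelemer, 3 to 10 by strain and 3524 to 5160 by B-cell deficiency, and 15358 to 15755 for the controls of both genotypes.

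For 299 results of named genes, 2801 of 2969 values under the other alternatives kept their side of the threshold, 132 lost and 36 gained the call. Direction was counted only for results called in the main model, of which 0 reversed. Of 5253 values with an array left out, 5004 kept their side of the threshold, 216 lost and 33 gained the call, and 0 called results reversed. Fits within a lot could not give a value for the difference by B-cell deficiency or the controls of both genotypes. Signal over background was not measured.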

Other observations

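The tests of array scale and of separate processing for the crofelemer arrays were chosen only after the results were seen.

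The arrays of crofelemer-treated mice shared levels that differ from those of other C57BL/6 mice with and without MDI. In crofelemer with control against control alone, C57BL/6, 8669 probe sets were called as deposited and 8496 after quantile normalization, of which 7077 were called both times, which argues against scale or spread as the whole cause. The balance turned, from 3916 higher and 4753 lower to 4387 higher and 4109 lower. Of 7185 probe sets called in lot 1, 91.3% had the same sign in lot 3 (6560), which argues against the lot. The lot 3 side rests on 1 control array with crofelemer and 2 without. Separate processing and the drug cannot be told apart, since 0 crofelemer arrays have a mean in the range of the others, and either may be the cause. Other differences between these sets of mice were not tested.

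Other splits of the arrays into groups of the same sizes were counted for each comparison. For MDI in BALB/c mice the 10 splits are too few to give a share under 0.05 (67 probe sets, highest other 0, and 1 split as high, the real one). For MDI in C57BL/6 mice 1 of 100 splits, the real one, was as high (3225, highest other 1001). The same held for MDI in B-cell deficient mice (8205, highest other 1910) and crofelemer with MDI (7232, highest other 4853). It also held for crofelemer with control (8669, highest other 6683) and the controls of both genotypes (15822, highest other 12935). These shares are under 0.05, so a random split is an unlikely source of these counts. The splits ignored the lots, so they do not speak to lot effects. The splits for crofelemer with MDI ignored the replicate numbers, and splits within the 3 same-numbered pairs would be too few for a share under 0.05. For MDI in crofelemer-treated mice 4 of 56 splits gave as many as the real 12 (highest other 150), so chance cannot be excluded for the count.

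In the controls of B-cell deficient against C57BL/6 mice, 11 of 15 circadian clock genes rose and 2 fell (median 1.13), and 9 of 14 glucocorticoid response genes rose and 2 fell (median 1.00), while camera called neither (adjusted p = 0.980 and 0.597) and the median of all probe sets was 0.54.

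The 2 arrays in no group had 7.85 and 11.99 for Muc5ac, 18.26 and 19.13 for Retnla, 9.25 and 12.38 for Slc26a4, 6.53 and 12.01 for Rnase2a, 13.16 and 10.85 for Tnc, and 8.64 and 10.79 for Cd79a.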
